A study of Arabidopsis thaliana with 9 samples.

How the data were processed

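Total RNA from Arabidopsis thaliana cultures was measured on 9 Affymetrix expression arrays, 3 for each of 3 genotypes. The genotypes were Columbia wild type, 35S:AGL15, in which the MADS-domain transcription factor gene AGL15 is driven by a constitutive viral promoter, and the agl15 agl18 double loss-of-function mutant. Per the labels, seeds germinated in shaken liquid culture with 4.5 µM of the synthetic auxin 2,4-D, 2% sucrose and 10 mM MES buffer, under 23 h of light and 1 h of dark, and tissue was frozen on day 10. Biotin-labelled cRNA was made from 4 µg of total RNA per sample. The replicate numbers were checked for pairing. After removal of the group means, 3 of the 9 pairs of arrays with the same number correlated above 0.1, so the numbers were not used to pair arrays. Pairs with different numbers ran from −0.64 (wild type replicate 3 and 35S:AGL15 replicate 2) to 0.68 (wild type replicate 1 and 35S:AGL15 replicate 2). Arrays of these 2 genotypes thus shared deviations that the numbers do not mark and that the fit leaves out.

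The authors deposited a single linear array intensity per probe set and array. The values were never negative, ran from 0.0293 to 33792 and were not logged. The mean intensity without the top and bottom 2% of probe sets was between 500.04 and 500.06 on every array, whereas the median intensity ran from 132 to 199, so the deposited arrays share a trimmed mean and were not quantile normalized. The summary method, the software and the background correction are not given in the sources used here.

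The deposited intensities were converted to log2 with no offset. Of 22810 probe sets, 64 control probe sets were left out and 22746 were tested. Group means were fitted to all 9 arrays with limma 3.58.1 (lmFit and eBayes, constant prior) in R 4.3.3, and each comparison was a contrast of group means. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 22746 probe sets within a comparison, with an adjusted p under 0.05 as the threshold. "Rose", "fell" and "called" refer to that threshold. Intensities are given as mean ± SD over 3 arrays, and log2 changes with the standard error from limma. The 27 probe sets for Bacillus control transcripts were all dim, and the highest of them on an array served as that array's background level. Where every array of a group lay below it, the fold is a bound against that level, and where both groups did, no fold is given. Nor is one given where 1 array of a group lay above it and the other arrays below. The number of arrays limits the precision of every value.

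The array annotation and the reference gene table (assembly TAIR10.1) gave 1 gene to 13513 probe sets, several to 503 and none to 8730. Among the 13513, the table had a symbol for 1580 and only a locus code for 11933. A gene without a symbol is named by its locus code. AGL15 has no probe set in this annotation, so its own transcript was not analysed here. The annotation gives probe sets no genome positions, and no positions are printed. Probe sets were not counted as genes unless stated. In a count of genes, the brightest probe set of each gene was used.

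The comparisons, the tests, 25 gene lists with 502 members, and the rule for naming genes were fixed before the data were examined. The rule took AGL15 and AGL18, then in each comparison with wild type the 10 largest rises and the 10 largest falls among called probe sets with a gene symbol whose groups did not overlap. For 35S:AGL15 against the double mutant it took 5 and 5. It added up to 4 called members of each gene list (up to 2 uncalled members if none passed) and up to 10 genes called in opposite directions. Of the 502 list members, 69 were measured. The 11 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 in the 2 comparisons with wild type, 22 tests adjusted together, with camera at an estimated correlation and fry beside it. Overlaps of the 2 comparisons with wild type were set against 100 simulations of unchanged genotypes that share the same wild type arrays. Families of at least 6 probe sets with a shared symbol prefix, and the organelle genes, were chosen after the data were seen.

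The fit was tested on simulated data with the observed spread. Alternatives fixed before the data were seen were quantile normalization, median centring, a filter on the dimmest 40% of probe sets, a fit on the arrays of the 2 groups compared, a replicate block, an intensity trend in the prior, array weights, a test against a 1.2-fold change, a minimum change of 1.5-fold, an offset of 32 before log2, and leaving out each array in turn. Alternatives chosen after seeing the data were scaling on 9 bacterial and phage spike-in control probe sets, a batch term for the arrays with brighter spike-in controls, raising low values to the background level, leaving out 35S:AGL15 replicate 3 together with double mutant replicate 1, and a restriction to nuclear genes with a known length, with and without removal of a length trend. The batch term is set only by 35S:AGL15 replicate 3 against replicates 1 and 2. With it, every comparison with the double mutant depends on that 1 array. Image files and probe-level values were not used here.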

Results

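Expression was measured in 10-day cultures of 3 genotypes, wild type, 35S:AGL15 and the agl15 agl18 double mutant, with 3 arrays each. By the description of the series, somatic embryo formation at the shoot apex is raised in 35S:AGL15 and lowered in the double mutant. Between 69.2% and 84.5% of the 22746 probe sets lay above the background level of their array, which ran from 13.7 to 40.5 intensity units. The correlation of log2 intensity between arrays of a genotype was 0.960 to 0.964 in wild type, 0.943 to 0.956 in 35S:AGL15 and 0.951 to 0.959 in the double mutant. Median intensity averaged 195 ± 6.02 in wild type, 166 ± 25.7 in 35S:AGL15 and 136 ± 4.94 in the double mutant (SD, n = 3). The first 2 principal components held 48.7% and 27.0% of the variance.

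AGL18, a MADS-domain gene related to AGL15 and mutated in the double mutant, had the same probe set in all comparisons (locus AT3G57390). Its intensity was 179 ± 9.55 in wild type, 66.4 ± 21.3 in 35S:AGL15 and 81.5 ± 27.8 in the double mutant (SD, n = 3). AGL18 thus fell 2.78-fold in 35S:AGL15 (log2 change −1.48, SE 0.29, adjusted p = 0.0353) and 2.27-fold in the double mutant (−1.19, SE 0.29, adjusted p = 0.0266). All 9 arrays stayed above their background level for AGL18, the position of the probe set relative to the insertion being not given in the sources used here. AGL18 in 35S:AGL15 and in the double mutant differed by −0.29 (95% confidence interval −0.96 to 0.38, adjusted p = 0.545). Both AGL18 calls ended under quantile normalization, with log2 changes of −1.16 and −0.67, and under median centring, with −1.23 and −0.67. Under spike-in scaling both AGL18 calls held, with −1.71 (adjusted p = 0.0298) and −1.99 (adjusted p = 0.00489). Leaving out any single wild type array also ended both calls, with AGL18 at −1.51 to −1.43 in 35S:AGL15 and −1.22 to −1.14 in the double mutant. The AGL18 call in 35S:AGL15 ended too without 35S:AGL15 replicates 1 (−1.37) or 2 (−1.33) and without double mutant replicates 2 or 3 (−1.48 each), and that in the double mutant without its replicates 2 (−1.09) or 3 (−1.02).

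The comparison of 35S:AGL15 with wild type asks which transcripts differ in the genotype labelled as expressing AGL15 constitutively. Both measured members of the seed storage and oil body list rose in 35S:AGL15. OLEO3, an oleosin of oil bodies, was 6.21-fold higher (1931 ± 526 against 317 ± 116, SD, n = 3, adjusted p = 0.0127), and PAP85, a vicilin-like storage protein, was 4.48-fold higher (243 ± 138 against 50.7 ± 15.2, adjusted p = 0.0382). Among called probe sets with a gene symbol, the largest rise was in the plant defensin gene LCR67, 27.0-fold (1798 ± 530.3 against 74.8 ± 51.5, log2 change 4.75, SE 0.43, adjusted p = 0.00331). The largest falls among probe sets with a symbol included the subtilase gene SBT4.12, 16.7-fold (33.2 ± 12.8 against 533 ± 94.4, adjusted p = 0.00343), and the sucrose transporter gene SWEET11, 10.1-fold (338 ± 63.4 against 3400.4 ± 407, adjusted p = 0.00244).

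Further rises in 35S:AGL15 were found in the U-box ubiquitin ligase PUB19 (7.66-fold), the cysteine proteinase CP1 (5.31-fold) and the root growth regulator UPB1 (4.39-fold). ZCF37 and the acyltransferase SDT were also called higher, but only 1 of 3 wild type arrays lay above background for each, so no fold is given. The cell wall enzyme XTH26 was at least 3.23-fold higher and the thionin THI2.2 at least 3.71-fold higher, since wild type lay below background. The formate dehydrogenase gene FDH fell 10.0-fold, the cytochrome P450 CYP71B26 8.76-fold and ATC, a relative of the flowering repressor TFL1, 7.32-fold. The sucrose phosphate synthase gene ATSPS4F and the beta-glucosidase BGLU33 were called lower with 1 of 3 arrays of 35S:AGL15 above background, so no fold is given. For CYP71B26, as for SBT4.12, 2 of the 3 were above it. ATSBT5.2 fell at least 1.96-fold. BGLU32 and RR22 were called lower from intensities at or near background in both genotypes (means 0.777 against 5.22 and 1.71 against 11.8), so no fold is given for them. These genes had adjusted p-values from 0.00347 to 0.0451. For each the 3 arrays of 35S:AGL15 lay all above or all below the 3 of wild type, as the rule for naming genes required. Some of these calls were not stable. ATSBT5.2 stayed past the threshold in 6, ATSPS4F in 11 and THI2.2 in 13 of 24 alternatives, and UPB1 in 11 of 25.

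**Figure D1:**
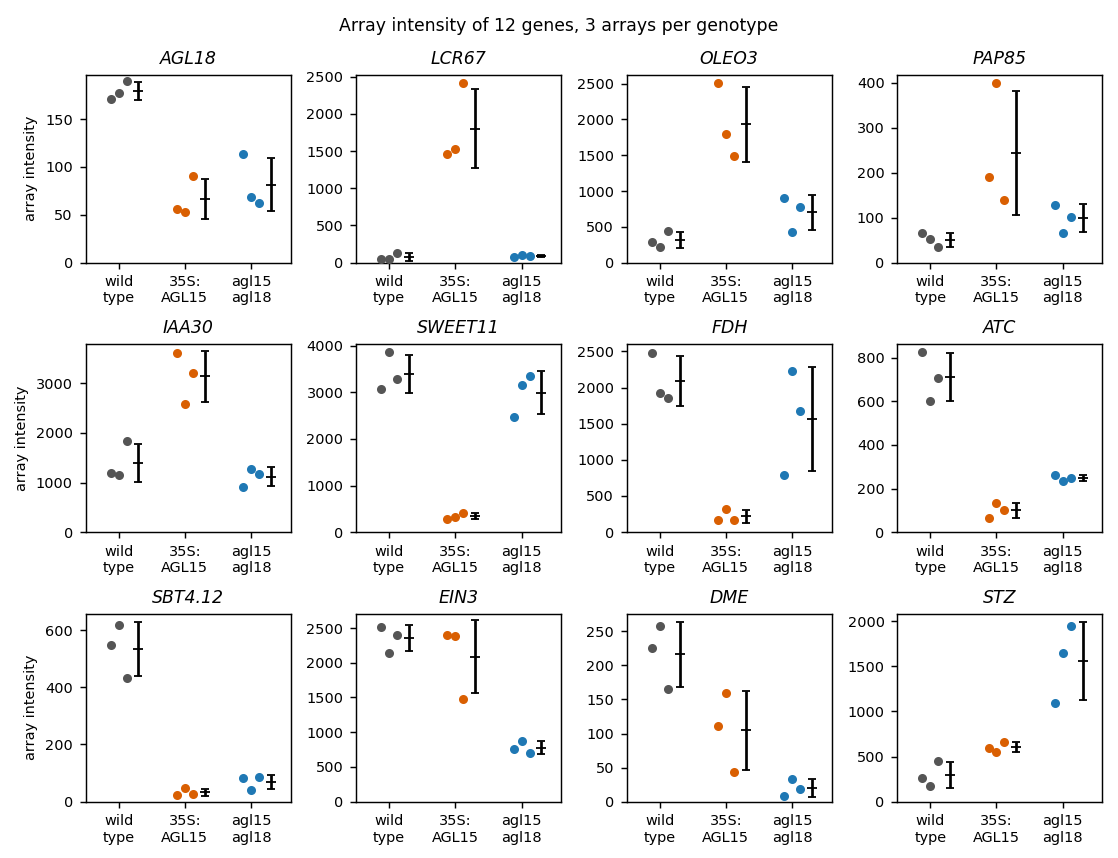
Array intensity (linear axis) of 12 genes in wild type, 35S:AGL15 and the agl15 agl18 double mutant. Points are single arrays, and the bar shows mean and SD of 3 arrays. LCR67 averages 1798 in 35S:AGL15 against 74.8 in wild type, and EIN3 averages 779 in the double mutant against 2351 in wild type.

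Among the other fixed lists, the auxin response repressors (Aux/IAA genes) had 3 of 7 measured members called in 35S:AGL15. IAA30 rose 2.29-fold (3138 ± 515 against 1394 ± 391, adjusted p = 0.0434), IAA20 rose 2.02-fold (1281 ± 229 against 636 ± 124, adjusted p = 0.0423) and IAA29 fell 2.22-fold (413 ± 138 against 889 ± 82.2, adjusted p = 0.0406). These calls were not stable, since of 25 alternatives IAA30 stayed past the threshold in 11, IAA20 in 9 and IAA29 in 10, with the direction kept in all and adjusted p-values up to 0.373, 0.502 and 0.170. WRKY53 stayed in 12 and PAP85 in 14 of the 25. In the flavonoid and anthocyanin list, AT4G14090, the anthocyanin glucosyltransferase UGT75C1, fell at least 3.79-fold (adjusted p = 0.0147) and the other 4 measured members did not pass. In the senescence list, WRKY53, a transcription factor of leaf senescence, fell 2.38-fold (81.2 ± 25.3 against 187 ± 8.07, adjusted p = 0.0348), with SAG29 at −1.53 (adjusted p = 0.0552) not past the threshold. No member of the remaining lists passed over all probe sets. Of the 2 measured embryo regulators, the seed transcription factor BZIP53 had a log2 change of 0.74 (adjusted p = 0.155) and BABY BOOM (BBM) of 0.03 (adjusted p = 0.965). The other regulators in that list, among them LEC1, LEC2, FUS3 and ABI3, were not analysed here because the annotation gives them no probe set.

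Adjusted over the list alone, BZIP53 (0.0291), GPDHC1 of seed oil synthesis (0.0192, log2 change −0.84), DEWAX of the ethylene list (AT5G61590, 0.00862, 1.05), COR15A of the abscisic acid list (0.00781, −1.28), LAS of the shoot meristem list (0.0272, −0.98), DFR of the flavonoid list (0.0402, −1.61), AT4G17260 of the hypoxia list (lactate dehydrogenase, 0.0106, 0.65) and SAG29 (0.00318) also had an adjusted p below 0.05 in 35S:AGL15. That adjustment does not correct for the number of lists. COR15A was the only measured member of its list, so its p-value was in effect unadjusted. BZIP53, DEWAX and LAS came from lists with 2 measured members each. In the lists with no member below 0.05 by either adjustment, the largest log2 changes in 35S:AGL15 were as follows. The desiccation list had AtLEA4-1 at 0.69, with M17 below background in both genotypes. Gibberellin signalling had GID1B at 0.47 and GID1A at 0.38, and auxin synthesis and transport had GH3.3 at −0.58. The cell cycle list had AUR2 at 0.46 and AUR1 at 0.35, wound and defence genes PDF1.2b at 0.55, the heat shock list ATHSP22.0 at −0.10, and leaf photosynthesis RCA at −0.50 and LHCB4.2 at −0.39. Root markers had EXPA18 at 0.63 and EXPA7 at 0.43, and stomatal markers had FMA at −0.99. No size is given for YUC4, ARR15, RR16, THI2.1, MUTE, AGL42 and AGL24, which had at most 1 of 3 arrays above background in 35S:AGL15 or in wild type. The lists of embryo programme repressors, gibberellin synthesis, gibberellin inactivation and vascular markers had no measured member.

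No list shift passed camera in 35S:AGL15 or in the double mutant (0 of 22 tests, also 0 with an estimated correlation). Without adjustment, 4 of the 22 camera tests had p under 0.05. The lowest adjusted p, 0.158, was reached by the flavonoid list (median log2 −0.83) and the senescence list (−1.25) in 35S:AGL15 and by the gibberellin signalling (0.55) and hypoxia (0.36) lists in the double mutant. By fry, which asks whether members move one way on balance, 5 tests passed. They were the senescence list in both genotypes (adjusted p = 0.0187 each), the hypoxia list in both (0.0187 and 0.00593) and the flavonoid list in 35S:AGL15 (0.0412). Only 3 of 15 members were measured for senescence, 3 of 15 for hypoxia and 5 of 20 for flavonoids. The hypoxia median was 0.10 in 35S:AGL15. Tested lists had 3 to 7 measured members, so neither camera nor fry speaks for the whole lists. Camera and the members differed in sign for the wound and defence list in 35S:AGL15 (median −0.04, camera up) and for the desiccation list in the double mutant (−0.11, camera up). In the double mutant the mean was negative while median and camera were positive for auxin synthesis and transport (mean −0.14, median 0.29) and for leaf photosynthesis (mean −0.06, median 0.12).

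In all, 838 probe sets were called in 35S:AGL15 against wild type, 313 higher and 525 lower, which is 170 genes higher and 260 lower. The median log2 change of all probe sets was −0.13. The share of lower calls was 62.6% with the deposited scaling, 48.7% under quantile normalization (418 higher, 397 lower), 42.1% under median centring (404 higher, 294 lower) and 75.4% under spike-in scaling (56 higher, 172 lower), where the median of all probe sets was 0.00, 0.12 and −0.36. Groups did not overlap for 23.0% of probe sets, against 10% by chance. In simulated data with 100 changes of each size, the test found 3% of 2-fold and 57% of 4-fold changes in 35S:AGL15. With 3 arrays per genotype most 2-fold changes were thus missed at that setting. Fewer probe sets changed there than were called here, so these shares may be too low for the real comparison. The count was 192, 191 and 422 without wild type replicates 1, 2 and 3, and 195 and 1867 without 35S:AGL15 replicates 1 and 2. Spike-in controls were brighter in 35S:AGL15 replicate 3 and the double mutant arrays than in the other 5 arrays, and by limma within those 5 arrays 47 probe sets were called. With this split as a term in the fit 566 were called, the same as when 35S:AGL15 replicate 3 was left out.

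The comparison of the double mutant with wild type asks which transcripts differ in the agl15 agl18 genotype. EIN3, the central transcription factor of ethylene signalling, fell 3.02-fold in the double mutant (779 ± 87.8 against 2351 ± 188, SD, n = 3, adjusted p = 0.00446). LD, a homeodomain gene of flowering time, fell 8.66-fold (41.9 ± 9.32, with 2 of 3 arrays above background, against 359.9 ± 59.7, adjusted p = 0.00277), and DME, a DNA glycosylase that removes methylated cytosine, fell by its most changed probe set (20.09 ± 12.7 against 216 ± 47.1, adjusted p = 0.00698, no fold given since 1 of 3 double mutant arrays lay above background), while its other probe sets changed by −1.38 (adjusted p = 0.0406) and −1.06 (adjusted p = 0.0552). STZ, a zinc finger gene of stress responses, rose 5.56-fold (1559 ± 432 against 295 ± 144, adjusted p = 0.00494).

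Of the 20 largest named changes in the double mutant, 8 were in organelle genes. Naming took only the 1580 probe sets with a gene symbol, and the organelle sets held 22 mitochondrial and 69 plastid probe sets. On the same arrays the 25S ribosomal RNA control was 1.85-fold and the spike-in controls 1.76-fold brighter than in wild type. A difference between the arrays and one between the genotypes cannot be told apart here. The mitochondrial genes nad1 (5.39-fold), nad5 (4.88-fold), both subunits of respiratory complex I, and ccb452 (4.32-fold, 1529 ± 74.8 against 354 ± 14.3), which acts in cytochrome c assembly, rose. The plastid genes for ribosomal proteins rpl22 (16.4-fold, 145 ± 51.5 against 2309.9 ± 328), rpl36 (12.4-fold), rpl14 (11.6-fold) and rpl16 (8.89-fold) fell, whereas the photosystem II gene psbI rose 5.95-fold (2594 ± 986 against 467 ± 283, adjusted p = 0.0321). Their adjusted p-values were 0.00173 to 0.00355 apart from psbI.

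Other rises in the double mutant were PUB19 (4.68-fold) and ZCF37 (no fold given, as above), which had also risen in 35S:AGL15. WSD1 and SDH2-1 were called higher with both genotypes below background, and SCPL32 with wild type below it, so no fold is given for these 3. Falls were found in BGLU33 (at least 7.23-fold), the chromatin remodeller CHR23 (at least 3.45-fold), the salicylate glucosyltransferase UGT74F1 (at least 1.52-fold) and SBT4.12 (8.06-fold). BGLU33 and SBT4.12 also fell in 35S:AGL15. The calls of SCPL32 and SDH2-1 stayed past the threshold in only 8 and 10 of 24 alternatives.

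**Figure D2:**
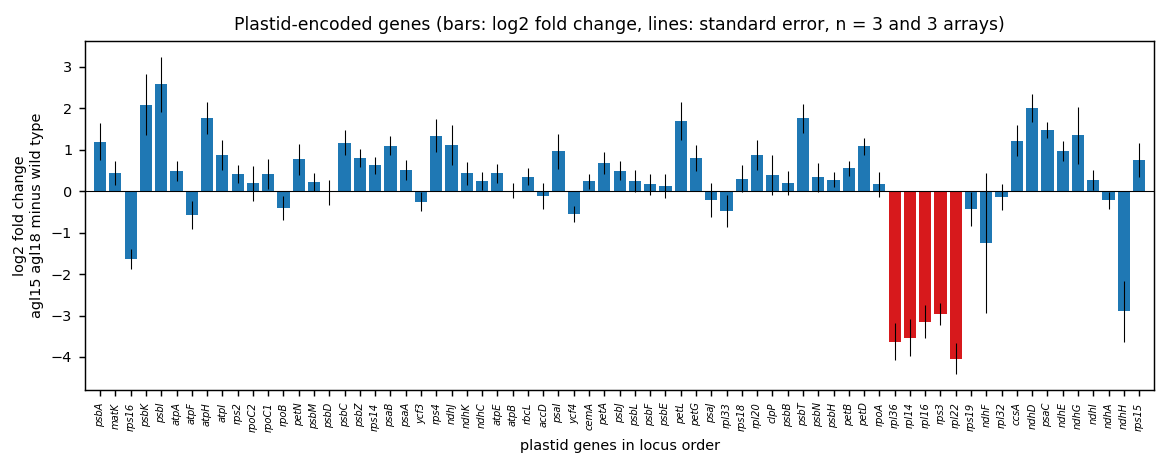
Log2 fold change of plastid-encoded genes in the double mutant against wild type, in gene order along the plastid genome, with standard errors (3 and 3 arrays). The red bars are rpl36, rpl14, rpl16, rps3 and rpl22, which are 7.80-fold to 16.4-fold lower, while rpoA and rps19 on either side were not called. The run was chosen after its values were seen.

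Of the fixed lists, 4 had a called member in the double mutant. Besides EIN3, the Calvin cycle kinase PRK fell 2.2-fold (244 ± 14.3 against 542 ± 98.5, adjusted p = 0.00872) and SAG29, a senescence-associated sucrose transporter, fell 3.63-fold (969 ± 346 against 3418 ± 628, adjusted p = 0.00996). AT4G17260, listed as lactate dehydrogenase in the hypoxia list, rose 1.65-fold (4454 ± 560.0 against 2691 ± 80.2, adjusted p = 0.0189), a call that stayed in 13 of 25 alternatives and a direction that turned to −0.08 under spike-in scaling. OLEO3 and PAP85, which rose in 35S:AGL15, had log2 changes of 1.14 (adjusted p = 0.0684) and 0.96 (adjusted p = 0.164) in the double mutant. BZIP53 was at 0.77 (adjusted p = 0.058) and BBM at 0.07 (adjusted p = 0.882). Adjusted over the list alone, BZIP53 (0.0238), OLEO3 (0.0311), AUR1 of the cell cycle list (0.0489, log2 change −0.54) and EXPA18 of the root markers (0.0489, 0.72) also had an adjusted p below 0.05 in the double mutant. Each came from a list with 2 measured members, and the number of lists was not corrected for.

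In the lists with no called member, the largest log2 changes in the double mutant were −1.08 for M10 and 0.51 for LEA4-5 in the desiccation list, −0.49 for GPDHC1 and 0.33 for AT3G44830 in seed oil synthesis, and 0.92 for GID1B and 0.63 for GID1A in gibberellin signalling. Aux/IAA genes had IAA33 at −0.73 and IAA29 at −0.64, and auxin synthesis and transport had GH3.1 at 0.88. No size is given for YUC6, ARR15, RR16, AGL42, AGL24 and FMA, which had at most 1 of 3 double mutant arrays above background. COR15A of the abscisic acid list was at −0.77. The shoot meristem list had LAS at −0.30, with CLV3 below background in both genotypes. DFR and AT5MAT of the flavonoid list were at −0.55 and −0.53, PDF1.2 of the wound and defence list at 1.08 and ATHSP22.0 of the heat shock list at −1.50.

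In total, 4304 probe sets were called in the double mutant, 886 higher and 3418 lower, which is 485 genes higher and 1950 lower. The median log2 change of all probe sets was −0.16, and groups did not overlap for 46.1% of probe sets, against 10% by chance. The share of lower calls was 79.4% with the deposited scaling, 56.3% under quantile normalization (1633 higher, 2101 lower), 27.9% under median centring (4082 higher, 1576 lower) and 99.0% under spike-in scaling (72 higher, 7372 lower), where the median of all probe sets was 0.06, 0.36 and −0.96. Which direction prevailed among the calls thus turned with the scaling. On simulated data the test found 2% of 2-fold and 57% of 4-fold changes in this comparison, and 88% of 4-fold changes when 200 were placed among the probe sets of above-median intensity. Far fewer probe sets changed in the simulations than the 4304 called here, which makes the simulated threshold stricter. These shares are thus likely too low for this comparison. The count was 2352, 1829 and 2433 without wild type replicates 1, 2 and 3, and 2243 without double mutant replicate 3. All double mutant arrays had brighter spike-in controls (1347 ± 317 against 765 ± 109 in wild type), so no count within a batch can be had, and with the split as a term in the fit 6 probe sets were called.

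The comparison of 35S:AGL15 with the double mutant sets the 2 altered genotypes against each other. LCR67 was 19.8-fold higher in 35S:AGL15 (1798 ± 530.3 against 88.6 ± 8.26, adjusted p = 0.00313), and CP1 11.2-fold higher (591 ± 180.3 against 54.4 ± 22.6, adjusted p = 0.00313). AtVEX1, a sugar transporter of the SWEET family, was called higher (97.4 ± 25.2 against 14.2 ± 11.9, adjusted p = 0.0465) with 1 of 3 double mutant arrays above background, so no fold is given, and stayed past the threshold in 9 of 24 alternatives. BGLU19 was at least 3.40-fold higher and XTH26 at least 1.99-fold higher. SWEET11 was 8.86-fold lower (338 ± 63.4 against 2989 ± 463, adjusted p = 0.000976) and FDH 6.97-fold lower (217 ± 88.9 against 1565 ± 719, adjusted p = 0.0081).

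RR22 was at least 1.38-fold lower in 35S:AGL15 than in the double mutant, and WSD1 and AGL33 were called lower with both genotypes below background (AGL33 in 11 of 24 alternatives). Of the genes named above, OLEO3 (log2 difference 1.5, adjusted p = 0.0336), IAA30 (1.49, adjusted p = 0.0113), IAA20 (1.27, adjusted p = 0.011) and EIN3 (1.39, adjusted p = 0.0101) were higher in 35S:AGL15 than in the double mutant, and CYP71B26 (−2.45, adjusted p = 0.00578) and STZ (−1.33, adjusted p = 0.0446) were lower. PAP85 (1.2, adjusted p = 0.102), SAG29 (0.33, adjusted p = 0.554) and SBT4.12 (−1.05, adjusted p = 0.096) did not pass this test.

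Between these genotypes the calls were 3567 probe sets, 2369 higher and 1198 lower in 35S:AGL15, with a median log2 change of 0.08 and no overlap for 33.9% of probe sets, against 10% by chance. The share lower was 33.6% with the deposited scaling, 47.7% under quantile normalization (1672 higher, 1526 lower), 67.6% under median centring (1210 higher, 2528 lower), and 5.64% under spike-in scaling (2376 higher, 142 lower). Under quantile normalization and median centring the median of all probe sets was close to 0 and −0.20. In simulated data 1% of 2-fold and 54% of 4-fold changes were found. Far fewer probe sets changed there than the 3567 called here, so these shares are likely too low. The count was 2153 without wild type replicate 2, 1032 without 35S:AGL15 replicate 1, and 2007, 2042 and 1162 without double mutant replicates 1, 2 and 3. Among the 4 arrays with brighter spike-in controls only 1 is 35S:AGL15, and the median log2 change there was 0.10. With the split as a term the comparison rests on the same array, with the same median, so no count is given for either.

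The series contrasts more with less AGL15 activity, which raises the question whether genes move in opposite directions in the 2 genotypes. The double mutant is also mutated in AGL18, so the genotypes do not differ in AGL15 alone. Of 341 probe sets called in both comparisons with wild type, 320 moved the same way, 128 higher and 192 lower, and 21 moved in opposite ways. ZCF37 and PUB19 rose and SBT4.12 and BGLU33 fell in both genotypes, and for ZCF37 (adjusted p = 0.572) and PUB19 (0.71, adjusted p = 0.306) the difference between the genotypes did not pass. Lists drawn independently would share 12.2 higher and 78.9 lower probe sets, and 47.0 and 20.4 in the opposite classes. That reckoning leaves out the shared wild type arrays, which push calls the same way. The simulations gave 0 calls in each class, so they cannot weigh these counts either. Simulated unchanged genotypes that share the wild type arrays gave a covariance of the log2 changes of 0.112 on average (highest 0.119), against 0.282 observed. The correlation across probe sets, which are not independent replicates, was 0.437, against 0.5 on average in the simulations.

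**Figure D3:**
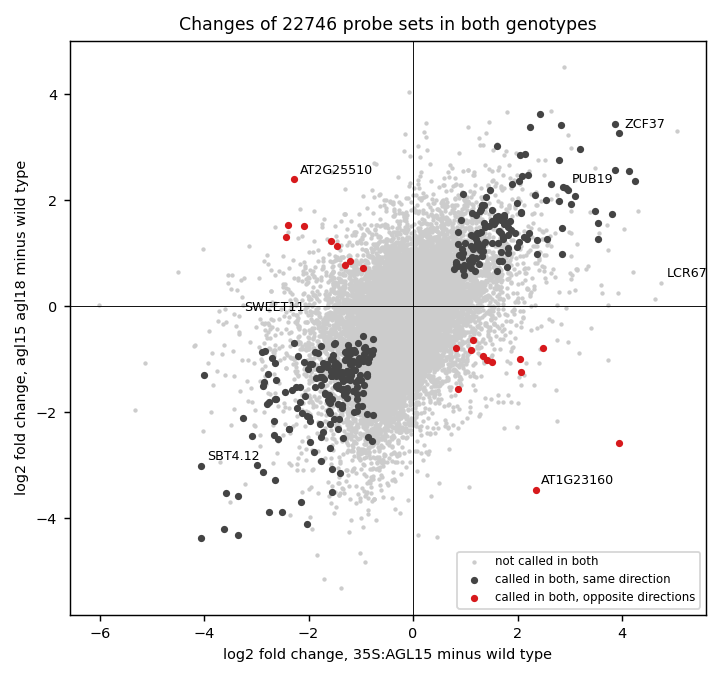
Log2 fold change against wild type of 22746 probe sets, in 35S:AGL15 (horizontal axis) and in the double mutant (vertical axis). Dark points are the 320 probe sets called in both in the same direction, and red points the 21 called in opposite directions.

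Of the 21 probe sets with opposite calls, 12 rose in 35S:AGL15 and fell in the double mutant and 9 did the reverse. The 9 with a single gene are known to the annotation by locus code only. AT1G23160 averaged 768 ± 301 in 35S:AGL15, 148 ± 55.0 in wild type and 14.0 ± 7.04 in the double mutant (SD, n = 3), where 1 of 3 arrays lay above background, so no size is given for the difference (adjusted p = 0.00176). AT2G43590 averaged 7677 ± 2472, 1828 ± 488 and 764 ± 169 in the same order, and AT5G50130 averaged 634 ± 96.3, 254 ± 67.8 and 129.8 ± 4.88. The reverse order held for AT2G25510, at 161 ± 85.5 in 35S:AGL15, 732 ± 265 in wild type and 3668 ± 379.6 in the double mutant (−4.67, adjusted p = 0.00313). AT1G51000, AT5G61890 and AT3G01930 also fell in 35S:AGL15 and rose in the double mutant, though AT5G61890 was at −0.03 in the double mutant under spike-in scaling. AT1G14240 and AT3G25790 rose in 35S:AGL15 and fell in the double mutant. Among these, 25 alternatives kept the calls of AT2G25510 in 35S:AGL15 in 11, of AT1G14240 in 11 for either genotype, of AT3G25790 in the double mutant in 12 and of AT5G61890 in the double mutant in 13. The widest difference belonged to a probe set that the annotation gives no gene, at 4918 ± 1531 in 35S:AGL15, 310.5 ± 28.2 in wild type and 53.0 ± 13.5 in the double mutant (6.53, adjusted p = 0.000255). It was chosen after its values were seen.

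The contrast that is 0 for equal and opposite responses in the 2 genotypes was called for 2382 probe sets, 469 positive and 1913 negative. The direction that prevailed turned with the scaling here too, with 808 positive and 989 negative under quantile normalization, 1741 and 708 under median centring, and 71 and 2488 under spike-in scaling. Without a single wild type array this count was 372, 63 and 558 for replicates 1, 2 and 3, without 35S:AGL15 replicates 1 and 2 it was 1320 and 4177, without double mutant replicate 3 it was 1093, and with the spike-in split as a term it was 8. The median of this contrast was −0.24 with the split as a term and −0.31 without it, and the term rests on 35S:AGL15 replicate 3. The same-direction count was 61, 52 and 152 without wild type replicates 1, 2 and 3, 77, 830 and 212 without 35S:AGL15 replicates 1, 2 and 3, and 163 without double mutant replicate 3. The opposite-direction count was 4, 3 and 8 without the wild type replicates, 6 and 61 without 35S:AGL15 replicates 1 and 2, 13 and 4 without double mutant replicates 2 and 3, and 35 under median centring. With the spike-in split as a term in the limma fit, 4 probe sets moved the same way and 0 in opposite ways (77 at an unadjusted p under 0.05 in both). That term leaves 6 calls in the double mutant and rests on 35S:AGL15 replicate 3, so these counts cannot decide how the genotypes overlap.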

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

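The tests of array scaling and of gene length in this part were chosen only after the results were seen. Values of control probe sets, which no comparison uses, stood out in the double mutant because each of its arrays lay above each wild type array. The 9 spike-in control probe sets, for bacterial and phage transcripts added to every sample, had a geometric mean of 1347 ± 317 in the double mutant and 765 ± 109 in wild type (SD, n = 3), 1.76-fold higher. The 25S ribosomal RNA control averaged 16852 ± 2585 against 9090.5 ± 1426, 1.85-fold higher. The background level averaged 29.2 ± 9.94 against 17.57 ± 3.64, 1.66-fold higher. For each, the exact permutation p was 0.1, the smallest that 3 against 3 arrays can give. In 35S:AGL15 the spike-in controls averaged 923 ± 304 (exact permutation p = 0.6 against wild type).

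In the double mutant, 79.4% of the 4304 calls were lower. The scaling of the arrays is a candidate explanation for this excess, since the share of lower calls was 56.3% under quantile normalization, 27.9% under median centring and 99.0% under spike-in scaling. A hybridization difference that the spike-in controls follow would also lower these probe sets in 35S:AGL15 replicate 3, whose spike-in controls were bright too, and that array lay at −0.30 against the other 35S:AGL15 arrays where the double mutant lay at −1.32, a ratio of 0.229. This single array leaves the question open, and since all 3 double mutant arrays had bright spike-in controls, the hybridization and the genotype cannot be told apart. A lower level of many transcripts in the agl15 agl18 genotype stays open as well and was not tested.

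Long genes tended to be lower and short genes higher in both genotypes, with a Spearman's rho of −0.354 in 35S:AGL15 and −0.323 in the double mutant across 7346 nuclear probe sets of the brighter part, which are not independent replicates. Genes of up to 1000 bp had median log2 changes of 0.18 and 0.23, and genes over 4500 bp of −0.38 and −0.60. In 35S:AGL15 the trend may be variation between arrays, since the slope of log2 intensity on log2 length ranged over 0.526 between its arrays, more than its mean difference from wild type of −0.21. On wild type replicates 1 to 3 the slope was 0.274, 0.187 and 0.0577. Both comparisons subtract these arrays, so a deviation of theirs alone could give a trend in both, which was not tested. In the double mutant the slopes lay below those of wild type on every array (mean difference −0.31, exact permutation p = 0.1, the smallest possible), so array variation and genotype cannot be told apart with 3 arrays each. RNA integrity stays open too, because the actin 3' to 5' ratio differed from wild type by −0.0094 in 35S:AGL15 with an SE of 0.062, too wide to exclude a rise of 0.1, and in the double mutant the actin ratio was 1.80 ± 0.465 against 1.41 ± 0.0825 (2.31, 1.68 and 1.40 on replicates 1 to 3), the ubiquitin ratio 1.18 ± 0.122 against 1.08 ± 0.0438 and the GAPDH ratio 1.01 in both (exact permutation p = 0.2, 0.4 and 0.9), and an effect of genotype on long genes was not tested.

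Splits of the 6 arrays of each comparison into other groups of 3 were counted. The real split gave 838 calls for 35S:AGL15 against wild type and the highest other split 0, 4304 and 1 for the double mutant against wild type, and 3567 and 3 for 35S:AGL15 against the double mutant. In each case 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.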

How the results depend on the processing

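Scaling on the spike-in controls, the spike-in split as a term or within its sides, raising values to the background level, leaving out 35S:AGL15 replicate 3 with double mutant replicate 1, and the restriction to nuclear genes of known length with or without removal of the length trend were chosen only after the data were seen. For each change listed here the cause was not tested. Fewer arrays or probe sets enter where arrays are left out, a smaller fit is used or genes are restricted. Some counts rose there all the same. The fit on the 6 arrays compared gave 5437 calls in the double mutant against wild type. Leaving out 35S:AGL15 replicate 2 gave 1867 in 35S:AGL15 and 5673 in the double mutant. Array weights ran from 0.26 for 35S:AGL15 replicate 2 to 3.91 for wild type replicate 2, and unequal spread was not tested. Counts with the spike-in split as a term that involve the double mutant rest on 35S:AGL15 replicate 3. Among 86 called results of named genes, 84 kept their direction under quantile normalization, median centring and spike-in scaling, 82 under every alternative run, 78 stayed past the threshold under quantile normalization, and 46 did so whichever array was left out. Over all alternatives, 2486 values of named genes kept direction and side of the threshold, 433 dropped below it, 63 rose past it and 37 changed sign. Both groups lay below background for 20, 72 and 74 of the calls in 35S:AGL15 against wild type, the double mutant against wild type, and 35S:AGL15 against the double mutant.

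The 838 calls in 35S:AGL15 against wild type became 320 with a replicate block, 6467 with array weights, 468 against a 1.2-fold change, 1525 with an offset of 32, 427 with 6 arrays, 228 under spike-in scaling, 1417 with values raised to background, 539 without both 35S:AGL15 replicate 3 and double mutant replicate 1, 337 among nuclear genes with a length, 409 after removal of the length trend, 47 within the 5 arrays with dimmer spike-in controls, and 191 to 1867 when an array was left out. For the double mutant, the 4304 calls became 9169 with array weights, 2632 against a 1.2-fold change, 7444 under spike-in scaling, 6 with the spike-in split as a term (3802 at an unadjusted p under 0.05), 2257 among nuclear genes, 2479 after removal of the length trend, and 1829 to 5673 when an array was left out. The median log2 change of all probe sets was −0.17 with the split as a term and −0.16 without it. Rises and falls cancel in that median, so it does not tell whether the changes became smaller. Between 35S:AGL15 and the double mutant, 3567 became 2066 with a block, 7921 with weights, 1650 against a 1.2-fold change, 867 with 6 arrays, 290 with the split as a term, 1687 among nuclear genes, 2072 without the length trend, 0 by limma within the 4 arrays with brighter spike-in controls (4867 unadjusted), where the lone 35S:AGL15 array is assumed to vary like the double mutant arrays, and 1032 to 4192 when an array was left out. The contrast for equal and opposite responses, 2382, became 1296 with a block, 8719 with weights, 4001 with the offset, 8 with the split as a term, 1141 among nuclear genes, 1378 without the length trend, and 63 to 4177 when an array was left out.

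Same-direction calls in both genotypes, 320, became 493 with the filter on dim probe sets, 115 with a block, 2880 with weights, 145 against a 1.2-fold change, 666 with the offset, 112 under spike-in scaling, 4 with the split as a term, 567 with values raised to background, 186 without both 35S:AGL15 replicate 3 and double mutant replicate 1, 140 among nuclear genes, 182 without the length trend, 1398 with an adjusted p in one comparison and an unadjusted p in the other, and 52 to 830 when an array was left out. Opposite calls, 21, became 35 under median centring, 56 with the filter, 8 with a block, 51 with an intensity trend, 384 with weights, 5 against a 1.2-fold change, 59 with the offset, 3 under spike-in scaling, 0 with the split as a term (77 unadjusted), 47 with values raised to background, 8 among nuclear genes, 5 without the length trend, 107 with an adjusted p in one comparison and an unadjusted p in the other, and 3 to 61 when an array was left out.

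AGL18 in 35S:AGL15, at −1.48, no longer passed under quantile normalization (−1.16), median centring (−1.23), a block, a 1.2-fold test or a fit on 6 arrays (−1.48 each), and ranged from −1.73 to −1.33 when an array was left out. In the double mutant AGL18 no longer passed under quantile normalization (−0.67), median centring (−0.67), a block or a 1.2-fold test (−1.19 each) or with the split as a term (−1.93), and ranged from −1.45 to −1.02 when an array was left out. No gene list passed camera, but 5 list tests passed with fry, 1 under spike-in scaling, 2 without both 35S:AGL15 replicate 3 and double mutant replicate 1, and 0 to 1 when an array was left out, the 1 being gibberellin signalling without double mutant replicate 1 (adjusted p = 0.0442).

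Of the gene values that changed sign, AT4G17260 (−0.0798) and AT5G61890 (−0.0259) in the double mutant under spike-in scaling, and BGLU32 (0.29) and RR22 (0.10) in 35S:AGL15 with values raised to background, had been called. The others had not passed. Under spike-in scaling these were AGL18 between 35S:AGL15 and the double mutant (0.28), in 35S:AGL15 BBM (−0.21) and AT5G10040 (−0.14), and in the double mutant BZIP53 (−0.0331), BBM (−0.73), LEA4-5 (−0.29), AT3G44830 (−0.47), GID1A (−0.17), PDF1.2b (−0.32) and MUTE (−0.20). With the split as a term, AGL18 between 35S:AGL15 and the double mutant was 0.21 and AT5G10040 in 35S:AGL15 −0.0535. Array weights gave PDF1.2b −0.82 in 35S:AGL15 and −0.18 in the double mutant. Quantile normalization gave AT5G10040 −0.0229 in 35S:AGL15, and median centring gave GPDHC1 0.0295 in the double mutant. Removal of the length trend gave AT5G10040 −0.41 in 35S:AGL15 and PDF1.2b −0.0706 in the double mutant. Values raised to background gave YUC6 0.46 and AT5MAT 0.13 in the double mutant. Without both 35S:AGL15 replicate 3 and double mutant replicate 1, AT5G10040 was −0.0535 in 35S:AGL15, and BBM −0.0271 and AT5MAT 0.12 in the double mutant. When an array was left out, BBM ran from −0.18 to 0.25, PDF1.2b from −0.0706 to 1.19 and AT5G10040 from −0.0535 to 0.25 in 35S:AGL15, and BBM from −0.0837 to 0.16, LEA4-5 from −0.13 to 1.15, AT5MAT from −0.88 to 0.12 and PDF1.2b from −0.0131 to 0.94 in the double mutant.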

Other observations

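The gene families and organelle sets in this part, 40 sets in 80 tests adjusted together, and the test of neighbouring plastid genes were chosen only after the data were seen. Transcripts encoded by the mitochondrial genome rose in the double mutant, with 17 of 22 probe sets called higher and none lower at a median of 3.20-fold (camera adjusted p = 1.14e-14, and adjusted p = 0.138 with an estimated correlation). Examples are the respiratory chain subunits cox1 (3104 ± 853 against 817 in wild type, adjusted p = 0.00725) and cox2 (529 ± 59.5 against 157, adjusted p = 0.00402). In 35S:AGL15, 4 of the 22 were called higher at a median of 1.49-fold (camera adjusted p = 1.22e-08, and adjusted p = 0.258 with an estimated correlation). The median log2 change in the double mutant was 1.68 with the deposited scaling, 1.94 under quantile normalization, 2.19 under median centring and 0.88 under spike-in scaling, and with the spike-in split as a term it was 1.5 with 0 called by limma. That term rests on 35S:AGL15 replicate 3. The spike-in controls, the 25S ribosomal RNA control and the mitochondrial transcripts were thus all brighter in the double mutant.

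Several nuclear families shifted in the double mutant by camera at the preset correlation, none of them with an estimated correlation. TRM genes, which help to place proteins on cortical microtubules, had 7 of 15 members called lower (median log2 −1.19, adjusted p = 0.00875, and 0.672 with an estimated correlation), among them TRM28, 4.64-fold lower, and TRM19, 4.00-fold lower. Calmodulin-binding IQD genes had 6 of 15 lower (−0.77, adjusted p = 0.0227, and 0.672), with IQD31 at 435 ± 101 against 1588 ± 54.0, and ubiquitin-specific protease genes (UBP) had 4 of 12 lower (−0.70, adjusted p = 0.0311, and 0.672), with UBP23 4.38-fold lower. Beta-glucosidase genes (BGLU) had 7 of 20 lower (−0.85, adjusted p = 0.0339, and 0.402). Prenylated RAB acceptor genes (PRA) had 4 of 11 higher (0.68, adjusted p = 0.00875, and 0.402), with PRA1.A1 1.87-fold higher, and tetraspanin genes (TET) had 1 of 15 higher, TET9 at 2.21-fold (0.53, adjusted p = 0.00875, and 0.284). Under median centring the median was −0.67 for TRM, −0.25 for IQD, −0.18 for UBP and −0.33 for BGLU, and under spike-in scaling −1.99, −1.57, −1.50 and −1.65, so the size depended on the scaling, and it turned to −0.12 for PRA and −0.27 for TET under spike-in scaling. Median gene length was 3055 bp for TRM, 2785 bp for IQD, 3951 bp for UBP, 3337 bp for BGLU, 1016 bp for PRA and 1549 bp for TET, against 2122 bp over the nuclear probe sets with a length, so these families move with the trend on gene length given among the results for a closer look. In 35S:AGL15, autophagy genes (ATG, median 0.47, 0 of 8 called, adjusted p = 0.0439) and calmodulin-like genes (CML, 0.21, 1 of 7 called, adjusted p = 0.0459) passed camera, both at 0.672 with an estimated correlation.

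Of 69 probe sets of plastid-encoded genes, 11 were called higher and 7 lower in the double mutant (median log2 0.39, and −0.41 under spike-in scaling, camera adjusted p = 0.00037, and adjusted p = 0.672 with an estimated correlation). In 35S:AGL15 0 were called by limma, and the set passed camera (median log2 0.22, adjusted p = 0.00264, and 0.672 with an estimated correlation). Of the 7 lower, 5 were rpl36, rpl14, rpl16, rps3 and rpl22, which follow each other among the measured genes and were 7.80-fold to 16.4-fold lower, whereas rpoA (0.16) and rps19 (−0.43) on either side did not pass. In 35S:AGL15 their log2 changes ran from −0.74 to −1.18 and did not pass. A candidate explanation is that they share a transcript or its processing. In a permutation of gene order a run as long as 5 had p = 0.0001 (100000 permutations), but it was run on the genes in which the run was seen, so it restates the pattern and leaves the explanation open. All 5 stayed called lower under quantile normalization, median centring and spike-in scaling, and none with the spike-in split as a term, where their median was −2.70. That term rests on 35S:AGL15 replicate 3.

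More probe sets changed the same way than opposite ways in the 2 genotypes, 320 against 21, and 2 explanations were tested, of which the trend on gene length was taken up after the data were seen. The excess was still there after a trend on gene length was removed. Among nuclear genes of known length, 97.3% of shared calls went the same way after its removal and 94.6% before. The shared wild type arrays can keep this share high by themselves, so it does not measure what the trend contributes. Chance values of the shared wild type arrays push both comparisons the same way, and the covariance exceeded the simulated mean by 0.170, with 0.119 the highest simulated value, while the correlation, 0.437, lay below the simulated mean of 0.5, and 3 wild type arrays cannot be divided between the comparisons and so a trait of these arrays beyond the simulated spread may still contribute. A response common to both genotypes stays open and was not tested. The design sets them opposite in AGL15 activity, but the double mutant is also mutated in AGL18. AGL18 was lower in both genotypes (log2 change −1.48 and −1.19), with calls that some alternatives ended.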
